A study of Arabidopsis thaliana with 18 samples.

How the data were processed

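The samples were shoot-apex-enriched tissue of Arabidopsis thaliana plants grown for 5 weeks in short days (8 h light and 16 h dark, 21 °C), per the labels' protocols. Chromatin was immunoprecipitated with antibodies against H3K27me3, H3K4me3 or histone H3 in the wild type and in the chr4 mutant. The labels gave 18 samples in 6 groups of 3 biological replicates.

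Per the submitters' processing notes, the tools and builds named were Bowtie and TAIR10. The peak caller and the normalization were not given in the sources used here. The deposited tables gave 1 row per peak and mark, with values for a pool called control and a pool called treat, per the file headers. The table names say that 3 replicates of each genotype were pooled, and no value per replicate was analysed here, so no spread between replicates could be computed and the depth of each library is unknown. The headers do not say which pool is the wild type. The table names list the wild type before the mutant, but no source used here says which place is control. Every ratio is therefore written as treat pool over control pool, and no genotype was assigned from the values.

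Total signal and height per peak were scores deposited by the authors without a stated unit. The median over peaks of the ratio of total signal to height was 6.47 in H3K27me3 and 6.05 in H3K4me3. Spearman's rho of mean total signal with peak length was 0.87 and 0.65. Without a unit, these values do not tell whether total signal is a sum over the peak. The log2 ratios were deposited by the authors, and they equalled the log2 of the ratio of both pools' total signals once a signal of 0 was set to 1. No fold is given where 1 pool was listed at 0.

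The column that the authors named FDR was used for the calls as deposited. It was checked on the files, and its values were whole multiples of 8.36e-05 (within 0.001 of a step) in both tables. They ran from 0 to 1, with a median of 0.38 for H3K27me3 total signal and 0.448 for H3K4me3 total signal. An even spread would put 511.4 of 10228 H3K27me3 peaks and 801.6 of 16032 H3K4me3 peaks below 0.05, and 874 and 1039 were there. For peak height the counts were 511 and 602. The tables also hold a log10 p-value per peak, which was not used for calls. For total signal it was below 0.05 at 9971 H3K27me3 and 14794 H3K4me3 peaks, and after a Benjamini-Hochberg adjustment at 9970 and 14767, so the FDR column is not that adjustment. How the FDR was computed was not given in the sources used here, so the share of false calls is unknown.

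The rules for calls, gene links, lists and named genes were fixed before the data were examined. A peak was called when the deposited FDR was under 0.05 and the total signals differed at least 1.5-fold. A gene took the peak that covered most of its body, with at least 150 bp. Counts of genes are of protein-coding genes, a choice made after the files were seen. Gene names and neighbours came from a gene table of TAIR10.1 with 27432 nuclear protein-coding genes, whose coordinates are not printed. Peak coordinates are those of the deposited tables. As a check that both builds line up, 58.4% of protein-coding genes took an H3K4me3 peak, against 45.7% with genes shifted by 2000 bp and 41.1% with genes shifted by 20000 bp.

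For each of 14 gene lists, the median log2 ratio of members with a peak was placed among 10000 random lists of the same size, matched on 10 classes of mean signal, when at least 3 members had a peak. Draws from large classes were made with replacement. The percentiles describe these pools and are no test across replicates. On simulated lists of 12 peaks, 3 of 100 unshifted lists lay outside the central 95% for H3K27me3 and 5 of 100 for H3K4me3. With a shift of 0.5 on the log2 scale, 51 of 100 H3K27me3 lists and 100 of 100 H3K4me3 lists did. The simulation shuffled the log2 ratios over all peaks, which removed any link between signal and spread. Its shares therefore need not hold for the gene lists. The random H3K27me3 lists matched to floral identity genes, for example, ran only from -0.32 to -0.17. Changes in both marks were compared with the count expected from independent lists, and Spearman's rho was taken across genes, which are not independent replicates.

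Named genes were 11 fixed genes, per mark up to 8 of the largest rises and 8 of the largest falls among called genes with a symbol and with at least median signal in the higher pool, up to 4 called members per list, and 5 genes per direction class of both marks. MRD1 and HEI10 share 1 H3K4me3 peak, which lies on 3 genes. Other peaks also lie on more than 1 gene, such as the AP1 H3K27me3 peak, which lies on 5. A value given for a gene is that of its whole peak, which can reach far beyond the gene. The AP1 H3K27me3 peak was 13630 bp long with 4055 bp in the gene. That of MYB53 was 7340 bp with 1540 bp in the gene, and that of SPL11 was 1570 bp with 418 bp. Alternatives changed the fold and FDR thresholds, the measure, the centring, filters on signal and width, and the gene link. The Benjamini-Hochberg adjustment of the deposited FDR, the removal of organellar and repeat windows, the filter on the higher pool, and 3 further choices of genes or gene links were chosen after seeing the data. Histone H3 had no table of its own among the files analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.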

Results

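H3K27me3, a mark of Polycomb-repressed genes, and H3K4me3, a mark found at the start of active genes, were mapped by ChIP-seq in apices of the wild type and of the chr4 mutant. CHR4, also named PKR1, is a chromatin remodeller of the CHD family. The deposited tables held 10228 H3K27me3 peaks with a median length of 1030 bp and 16032 H3K4me3 peaks with a median length of 960 bp. Each peak had 1 value per pool of 3 replicates, so no difference below could be set against the spread between replicates. The headers name the pools only control and treat and do not say which is the mutant (the table names list the wild type before the mutant, which does not settle it), so directions are of the treat pool against the control pool.

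The targeted gene gave no check of the labels. CHR4 carried an H3K4me3 peak on chromosome 5 (18092650 to 18093880) with a total signal of 25726 in the control pool and 24676 in the treat pool. No H3K27me3 peak met the overlap rule at CHR4.

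The first comparison asked where H3K27me3 differed between the genotypes. Of the floral regulators and other genes fixed beforehand, none with an H3K27me3 peak passed the threshold. AP1, a floral meristem identity gene, had a signal of 66064 in the control pool and 56273 in the treat pool. SEP3, a floral organ identity gene, had 84426 and 68953. LFY, a master regulator of flower formation, had 68228 and 53334, and FUL had 72008 and 64019. The floral repressor FLC had 87091 and 71448, the organ identity gene AG 67348 and 65201, the meristem gene STM 69598 and 53913, and the floral integrator SOC1 46228 and 48157. SPL4, a target of the age pathway, had 19042 and 9395, a 2.03-fold difference that did not pass, with an FDR of 0.107 in the authors' deposited table. SPL15 had no H3K27me3 peak under the overlap rule.

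The largest H3K27me3 falls among named genes with ample signal began with SPDS2, which encodes a spermidine synthase. Its peak (chromosome 1, 26485500 to 26487340) went from 28384 in the control pool to 21 in the treat pool. NAC016 went from 13108 to 225, MYB53 from 37731 to 1544, and SPL11, a member of the age pathway, from 26445 to 1739, a 15.2-fold difference. ASY2 was 13.8-fold lower, UBC11, a ubiquitin-conjugating enzyme, 8.5-fold lower, ORP2A 8.42-fold lower and AT59 8.05-fold lower. The same rule, with its requirement on signal, was met by 62 named genes that were lower and only 3 that were higher. Among all protein-coding genes with a peak, 79 were called higher and 200 lower. The excess of falls comes partly from the rules on overlap and signal. Peaks called higher had a median length of 150 bp, equal to the smallest overlap that links a gene, and short peaks had low signal. Over all peaks 473 were higher and 399 lower, and with a 1 bp overlap 130 genes were higher and 232 lower. TIP2;3, an aquaporin, was 2.79-fold higher in the treat pool, BGAL7 1.97-fold higher and the calcium sensor CBL8 1.87-fold higher. Of 61 calls at named genes over both marks, 41 held with peak height, 27 with the filter on mean signal, 37 with a filter on the higher pool and 14 with a peak over 50% of the gene body.

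In all, 473 H3K27me3 peaks were higher and 399 lower in the treat pool. Of 6770 protein-coding genes with a peak, 79 were higher and 200 lower. Called genes were 4.12% of those with a peak, against 8.53% of all peaks, and 282 genes passed without a fold limit. These gene counts are no more than an even spread of the FDR would put below 0.05. These calls rest on the deposited FDR, whose computation was not given. A Benjamini-Hochberg adjustment of the deposited FDR, chosen after seeing the data, treats that FDR as a p-value. It left 2 H3K27me3 peaks and 0 genes. Both peaks were higher, and they lay in a chromosome 3 repeat (14201870 to 14202020) and in the chloroplast genome. Both had a deposited FDR of 0, which the adjustment cannot raise. Since the FDR moves in steps of 8.36e-05, a peak 1 step above 0 passes only if many peaks tie with it or lie below. A call lost under this adjustment therefore says little about that gene. The peaks called higher were short, with a median of 150 bp, against 480 bp for those called lower and 1140 bp for those not called. Leaving out peaks below the lower quartile of mean signal left 70 higher and 165 lower, so the share of higher calls went from 54.2% to 29.8%. The mean of both pools is low also where 1 pool lost its signal, and a filter on the higher pool, chosen after seeing the data, left 236 higher and 255 lower, a share of 48.1%.

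**Figure D1:**
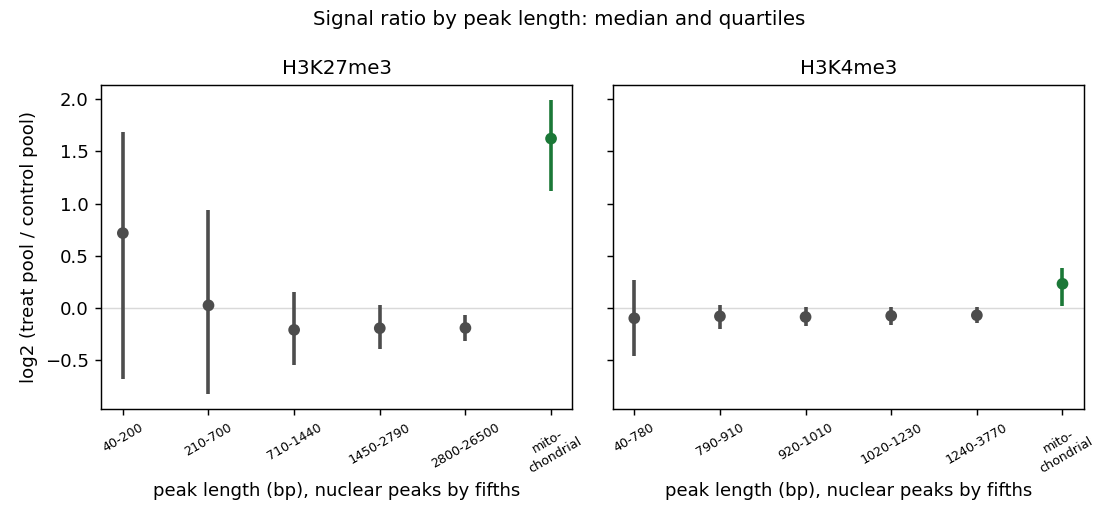
Median log2 ratio of treat over control pool (points) with quartiles (lines) for nuclear peaks in 5 classes of length in bp, and for mitochondrial peaks, per mark. H3K27me3 peaks of 40 to 200 bp had a median of 0.72 and those of 2800 to 26500 bp a median of -0.19, and mitochondrial H3K27me3 peaks had a median of 1.62.

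The second comparison asked the same of H3K4me3. CHR23, a chromatin remodelling ATPase, had the largest rise among named genes with ample signal, from 6973 in the control pool to 23553 in the treat pool. WIT1, a nuclear envelope protein, was 1.7-fold higher, MMT 1.52-fold higher and PDE345 1.5-fold higher. The largest fall under the same rule was at the peak shared by MRD1 and HEI10, the latter a regulator of meiotic crossovers (chromosome 1, 19963070 to 19964800), from 35190 to 3999, an 8.8-fold difference. That peak lies on 3 genes. INDH was 1.61-fold lower, and MBD7, which binds methylated DNA, 1.5-fold lower. Of the fixed genes, SPL15, which promotes flowering with age, had 16681 in the control pool and 11083 in the treat pool, a 1.51-fold difference close to the fold limit, with an FDR of 0.0483 in the authors' deposited table. The SPL15 call was lost with either recentring, at 2-fold, at an FDR under 0.001, with the adjusted FDR and with peak height. Its peak dropped out with either filter on signal and with a peak over 50% of the gene body. SPL15 gave way to another gene where each peak counted once. SOC1 had 11736 and 9538 and STM 7386 and 5998, and neither passed. AP1, SEP3, FUL, LFY, SPL4, FLC and AG had no H3K4me3 peak under the overlap rule.

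Across the genome 395 H3K4me3 peaks were higher and 564 lower. Of 16032 protein-coding genes with a peak, a count that equals the number of peaks by coincidence, 190 were higher and 377 lower. Called genes were 3.54% of those with a peak, and 644 passed without a fold limit. Here too, the gene counts are no more than an even spread of the FDR would put below 0.05. After the same adjustment 2 H3K4me3 peaks were left, both higher and both on chromosome 3 (14195720 to 14195870 and 14201880 to 14202010), and 0 genes. Both of these peaks also had a deposited FDR of 0. Leaving out peaks below the lower quartile of mean signal left 26 higher and 25 lower, and the filter on the higher pool left 38 higher and 49 lower.

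The lists of flowering, hormone and meristem genes were compared next. In the gibberellin list, 2 of 10 members with an H3K27me3 peak were lower: GA3OX1, the enzyme of the last step to active gibberellin, 9.62-fold, and RGL3, a DELLA repressor, 3.29-fold. In H3K4me3, 3 of 11 members were higher: GA20OX1, a biosynthetic enzyme, 3.16-fold, RGL3 2.86-fold and GA2OX2, a degrading enzyme, 1.88-fold. Either filter on signal left 0 of 6 H3K4me3 members higher, as did asking for 50% of the gene body, and peak height left 2 of 11. The GA3OX1 H3K27me3 peak dropped out with the filters on signal and on width, and peak height left 1 member lower. With a peak over 50% of the gene body, 0 of 3 H3K27me3 members were lower. The members include enzymes of synthesis and of degradation and a repressor. In the shoot meristem and boundary list, CUC3, a boundary gene, was 3.81-fold lower in H3K27me3 as 1 of 9 members (2 of 9 with peak height and 0 of 7 with a peak over 50% of the gene body), and KNAT2, a homeobox gene, 2.27-fold higher in H3K4me3 as 1 of 6. The KNAT2 call was lost with peak height and with the filters on signal and on width. In the SPL list, SPL11 was lower in H3K27me3 as 1 of 2 members, and in H3K4me3 SPL11 was 1.86-fold higher and SPL15 lower of 7. The H3K4me3 calls of SPL11 and SMZ were lost at 2-fold, with peak height and with either filter on signal. They were also lost at an FDR under 0.001 and with the adjusted FDR. That of SMZ was lost with a peak over 50% of the gene body as well. Among floral repressors, SMZ was 1.86-fold lower in H3K4me3 as 1 of 12, and 0 of 7 passed in H3K27me3.

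No member passed in either mark in the other lists under the main settings. Alternatives called 2 of 7 auxin genes lower in H3K27me3 with a 1 bp overlap and 1 of 7 with 500 bp added on both sides. Peak height called 1 root gene lower in H3K27me3 and 1 auxin gene higher in H3K4me3. Without a fold limit 1 auxin gene was higher in H3K4me3. With H3K27me3 peaks there were 16 of 17 floral identity genes, 11 of 12 seed maturation genes, 7 of 8 root genes, 5 of 10 auxin genes, 4 of 9 photoperiod genes, 4 of 8 leaf development genes, 2 of 16 Polycomb and trithorax genes and 1 of 4 CHD remodellers. With H3K4me3 peaks there were 15 Polycomb and trithorax genes, 8 of 8 ubiquitously expressed genes, 7 of 7 photosynthesis genes, 6 leaf development genes, 5 auxin genes, and 3 each of the CHD remodellers, the floral identity and the photoperiod genes.

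Of 21 list medians, 4 lay outside the central 95% of matched random lists, where 1.05 would by chance. The shoot meristem and boundary list had a median H3K27me3 log2 ratio of -0.43, at percentile 0.615, and the gibberellin list -0.40, at percentile 2.07. The floral identity list had -0.15, at percentile 99.6, so it lay above matched genes, whose random lists had a median of -0.25. With peak height in place of total signal its percentile was 78.2. Of the 10 alternatives that can change a percentile, the gibberellin list lay outside the range in 5. All peaks had a median H3K27me3 log2 ratio of -0.14, and -0.08 for H3K4me3. The photosynthesis list, markers of green leaf tissue, had a median H3K4me3 log2 ratio of 0.10, at percentile 99.9. The other H3K27me3 medians were -0.44 for auxin (percentile 2.73, and outside the range in 7 of those 10 alternatives), -0.35 for photoperiod, -0.30 for seed maturation, -0.25 for leaf development, -0.21 for floral repressors and -0.11 for root genes. The other 11 H3K4me3 medians ran from -0.14 to 0.041, all within the central 95% of their random lists; with peak height the CHD remodeller list lay outside, at percentile 1.31.

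**Figure D2:**
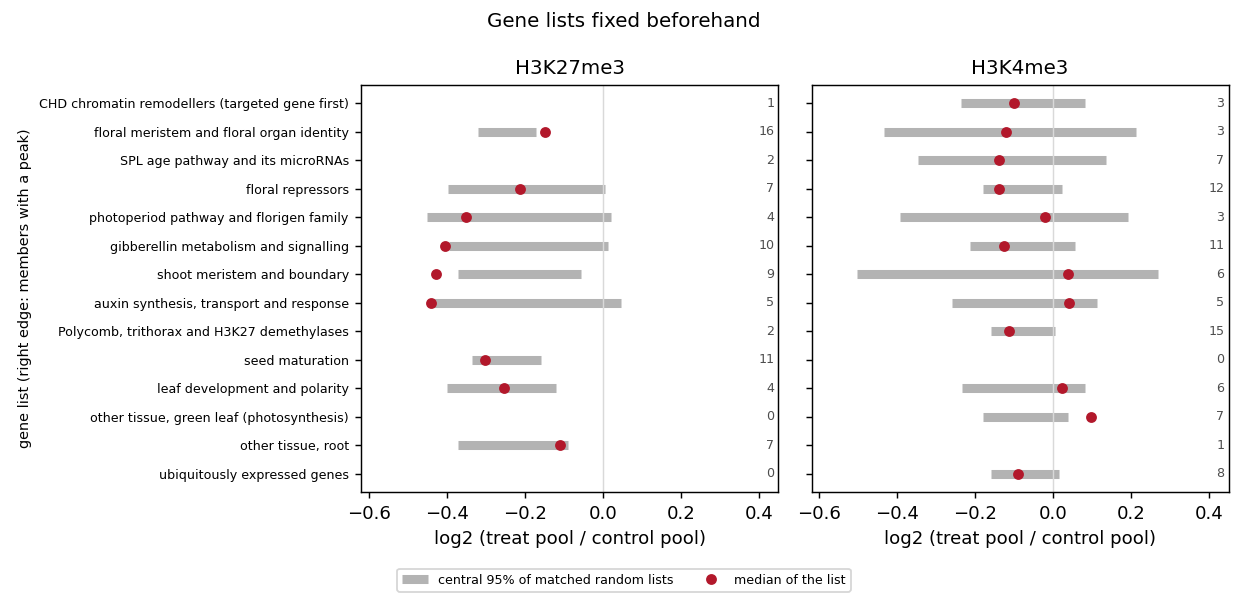
Median log2 ratio of treat over control pool for each gene list (points) beside the central 95% of 10000 matched random lists (bars), for H3K27me3 on the left and H3K4me3 on the right, with the number of members with a peak at the right edge. The shoot meristem list lies at -0.43 and the floral identity list at -0.15 in H3K27me3, on opposite sides of their bars, and the photosynthesis list lies at 0.10 in H3K4me3.

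The last comparison asked which genes changed in both marks. Of 920 genes with a peak of each mark, 13 were lower in H3K27me3 and higher in H3K4me3, against 5.69 expected from independent lists. The 5 with the largest sum of both absolute log2 ratios were AT4G25320, CYP86A4, AT2G36430, UBC11 and MOT1. AT4G25320 went from 22194 to 54 in H3K27me3 and from 985 to 23148 in H3K4me3. CYP86A4, a cytochrome P450, was 1.75-fold higher in H3K4me3, UBC11 6.51-fold higher and the molybdate transporter MOT1 2.05-fold higher. In the opposite direction 10 genes were found, against 1.96 expected. They included AT1G67330, from 581 to 16341 in H3K27me3 and from 14164 to 36 in H3K4me3, ABCI19, AT1G05400, AT3G26480 and GATA12, a transcription factor gene. AT3G26480 and GATA12 were listed at 0 in the control pool for H3K27me3.

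Both marks were lower at 4 genes, against 6.65 expected: COR413IM1, HAF2, AT4G33560 and AT3G25510. HAF2, a histone acetyltransferase gene, was 7.41-fold lower in H3K27me3 and 26.0-fold lower in H3K4me3. Its H3K27me3 peak (chromosome 3, 6569760 to 6572040) and its H3K4me3 peak (6567980 to 6568730) did not overlap. The peaks of the 2 marks did not overlap at ABCI19 either, but they did at AT4G25320. Both were higher at 3 genes, against 1.67 expected: AT2G16586, AT2G01008 and AT3G41762, of which the last 2 lie in repeat windows at the start of chromosome 2 and on chromosome 3. Spearman's rho across the 920 genes was -0.15, as a description across genes that are not independent replicates. With the adjusted FDR no gene passed in both marks, and the filter on mean signal left 1 gene with opposite changes. With the filter on the higher pool, 3 genes were lower in H3K27me3 and higher in H3K4me3 and 2 the other way.

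**Figure D3:**
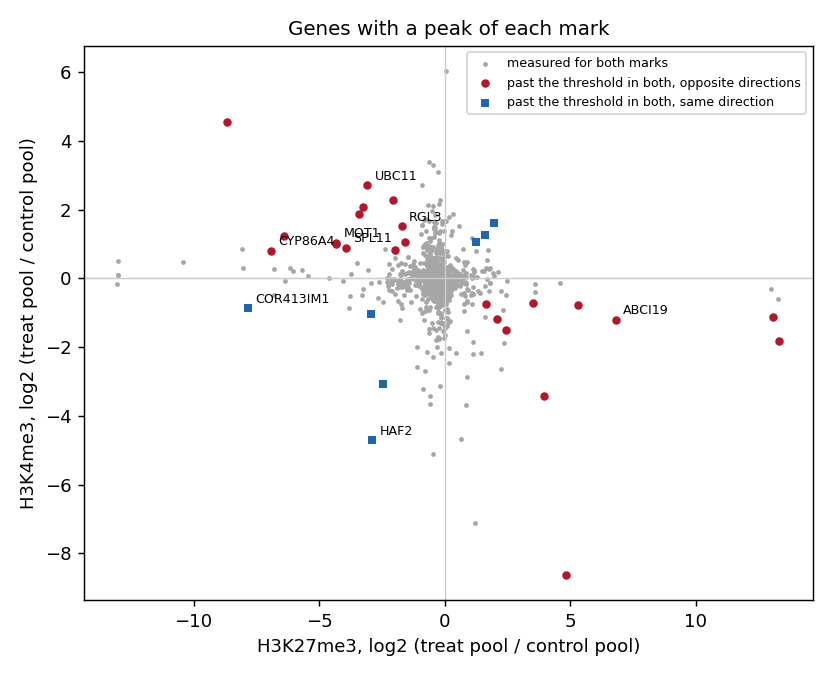
Each point is 1 of 920 genes with a peak of each mark, with the H3K27me3 log2 ratio of treat over control pool on the horizontal axis and the H3K4me3 log2 ratio on the vertical axis. Genes past the threshold in both marks are coloured, 23 in opposite directions and 7 in the same direction; points beyond 13 on the horizontal axis have a pool listed at 0, which the deposited ratio sets to 1.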

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

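All tests in this part were chosen after the result was seen. Signal from the organelles, which belongs to no comparison of the genotypes, differed between the pools. The median log2 ratio of treat over control was 1.62 over 32 mitochondrial H3K27me3 peaks and 1.53 over 2 chloroplast peaks. For H3K4me3 it was 0.23 over 38 mitochondrial peaks and 0.37 over 2 chloroplast peaks.

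Outside 3 repeat windows, 1991 short nuclear H3K27me3 peaks of at most 200 bp had a median log2 ratio of 0.67. Of these, 1274 were higher in the treat pool, 284 were called higher and 128 called lower, while all 32 mitochondrial peaks were higher. Reads shared with the mitochondrial insertion on chromosome 2 cannot be the whole source, since its window held 3.29% of the nuclear peaks called higher. More background in the treat H3K27me3 pool may account for the peaks called higher. Organelle DNA carries no nucleosomes, and the mitochondrial median of 1.62 exceeded that of the short nuclear peaks. Whether background also bears on the peaks called lower was not tested, and the normalization was not given. A difference between the genotypes at these sites stays open and was not tested, since each genotype is 1 pool. In the insertion window itself (chromosome 2, 3200000 to 3600000), the H3K27me3 median of 1.25 lay nearer to the mitochondrial value than to that of other short peaks, as did the H3K4me3 median of 0.27, which is consistent with reads shared with the mitochondrial genome.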

How the results depend on the processing

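The counts depended strongly on the deposited FDR, on the filters on signal and on the gene link, and the cause was not tested except where a filter removes peaks by its construction. No paired analysis was possible because only pooled values were analysed here, so the shared replicate numbers could not be used as a block; for the same reason no replicate was left out and no other split of the samples was made. The gene link with 500 bp upstream and the window around the gene start were not run, since the gene table gives no strand. Of the counts, 99 stayed within 1.5 times the main value, 69 were lower and 4 higher. Of the list medians under the alternatives other than the 4 that change only the calling threshold, 228 moved by less than the distance from the middle to the edge of the central 95% of matched random lists, and 8 by more, 6 of them by recentring, which shifts every gene alike and leaves percentiles as they were. Of 61 calls at named genes, all were lost with the adjusted FDR, and 6 held at an FDR under 0.001, 14 with a peak over 50% of the gene body, 27 with the filter on mean signal, 37 with the filter on the higher pool, 41 with peak height, 48 at 2-fold, 49 with the width filter, 57 without organelles and repeat windows, 58 with 500 bp added, 59 with either recentring and 59 with 1 gene per peak. All 61 held with a 1 bp overlap, all gene types or no fold limit, but by their construction these settings cannot remove a call, so they are no check.

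With the Benjamini-Hochberg adjustment of the deposited FDR, chosen after seeing the data, 2 H3K27me3 peaks were higher and 0 lower. For H3K4me3, 2 peaks were higher and 0 lower. In either mark 0 genes were higher or lower, and all 4 classes of both marks held 0 genes. Every peak left had a deposited FDR of 0, so this setting largely reflects the steps of that FDR. At a deposited FDR under 0.001, 13 H3K27me3 peaks were higher and 0 lower, with 1 gene higher and 0 lower, and 18 H3K4me3 peaks were higher and 1 lower, with 5 genes higher and 2 lower. There, both marks were higher at 1 gene, and the other 3 classes held 0.

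With peak height, 239 H3K27me3 peaks were higher and 252 lower, with 38 genes higher, a share of higher genes of 16.2% against 28.3%. For H3K4me3, 223 peaks were higher and 316 lower, with 111 genes higher and 221 lower. Lower H3K27me3 with higher H3K4me3 was left at 7 genes and both lower at 1. The floral identity H3K27me3 median became -0.27 and its percentile 78.2, and the CHD remodeller H3K4me3 median became -0.28, at percentile 1.31. At least 2-fold left 220 genes lower in H3K4me3.

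Without peaks below the lower quartile of mean signal, which also removes peaks lost in 1 pool, 70 H3K27me3 peaks were higher and 165 lower, with 25 genes higher, and 26 H3K4me3 peaks were higher and 25 lower, with 14 genes higher and 23 lower. Opposite changes were then left at 0 genes (H3K27me3 lower) and 1 gene (H3K27me3 higher), and both lower at 0. With the filter on the higher pool, chosen after seeing the data, 236 H3K27me3 peaks were higher and 255 lower, and 38 H3K4me3 peaks were higher and 49 lower, with 25 genes higher and 48 lower. Opposite changes were then left at 3 genes (H3K27me3 lower) and 2 genes (H3K27me3 higher), and both lower at 0. Without peaks under 300 bp, 115 H3K27me3 peaks were higher and 247 lower, with 48 genes higher, and 168 H3K4me3 peaks were higher and 360 lower. Higher H3K27me3 with lower H3K4me3 was then left at 6 genes and both higher at 0.

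With a peak over at least 50% of the gene body, 17 genes were higher and 93 lower in H3K27me3 and 21 higher and 61 lower in H3K4me3. The opposite classes then held 1 gene each, both lower 1 and both higher 0, and Spearman's rho was -0.23. With a 1 bp overlap, 130 genes were higher in H3K27me3 and 9 lower in both marks. With 500 bp added on both sides of the gene, chosen after seeing the data, 8 genes were lower in both marks, rho was -0.079, and AT3G41762 took another H3K4me3 peak with a log2 ratio of -0.024, the reverse of its main direction. All gene types gave 7 genes higher in both marks, and leaving out organelles and repeat windows gave 1; both were chosen after seeing the data.

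Recentring left every percentile as it was. Recentred on the median, the H3K27me3 medians were -0.0079 for floral identity, -0.16 for seed maturation, -0.11 for leaf development and 0.030 for root genes. Recentred on summed signals, floral identity was -0.045 and seed maturation -0.20. The shoot meristem H3K27me3 and photosynthesis H3K4me3 medians lay outside the central 95% in 10 of the 10 alternatives that can change a percentile, floral identity in 9, auxin in 7 and gibberellin in 5. The auxin percentile ran from 0.21 to 10.5.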

Other observations

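The tests of repeat windows, of resampled pairs, of leaf tissue as a source and of neighbouring peaks were chosen after the result was seen. Most peaks in 2 repeat windows were higher in the treat pool; the windows were picked after their values were seen, and what repeats they hold is background knowledge that was not checked against sequence. At the start of chromosome 2 (0 to 12000), 6 of 7 peaks were called higher in each mark, with a median log2 ratio of 1.77 for H3K27me3 and 1.34 for H3K4me3. In the chromosome 3 window, 8 of 11 H3K27me3 peaks and 7 of 14 H3K4me3 peaks were called higher, and 2 were called lower in each mark.

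Genes that changed in both marks did so in opposite directions more often than independent lists give, 23 against 7.65. The filter on mean signal left 1 such gene, and a filter on the higher pool left 3 lower and 2 higher in H3K27me3. With a peak over 50% of the gene body, 1 was left in each direction. These settings also cut the H3K4me3 gene calls from 567 to 37, 73 and 82. No expected count is given for them, so they do not tell whether the excess remains. Spearman's rho across 906 distinct peak pairs was -0.15, with a 95% interval from -0.21 to -0.08 over resampled pairs. Peak pairs are not replicates, so the interval holds no spread between libraries and is no test of the genotypes. A different share of leaf tissue in the pools may contribute, since the photosynthesis list's H3K4me3 median lay at percentile 99.9 of matched random lists. That median was only 0.10, with 0 of 7 members called. In the shoot meristem list H3K4me3 was not lower in the treat pool (median 0.038, percentile 83.5), and H3K27me3 was lower (-0.43, percentile 0.615). These lists therefore do not point 1 way. A different share of leaf tissue cannot be told apart from an effect of the genotype, because the genes that changed cannot be split by tissue. With the adjusted FDR 0 genes were called in both marks, but that adjustment left only peaks with a deposited FDR of 0. The count of 23 thus rests on the deposited FDR as it is. The rho uses no calls.

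At MRD1 and HEI10 the H3K4me3 peak was 8.8-fold lower in the treat pool. A deletion that took in a neighbouring peak would lower it too, but the larger absolute log2 ratio of both neighbours was 0.40, below the 1.5-fold limit. The neighbours lie 6180 and 3630 bp away, so a shorter deletion or a strain variant could still be the source and was not tested, since no H3 signal was analysed here, and so was an effect of the genotype.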
